A study of Mus musculus with 3 samples.

How the data were processed

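Gene expression was measured in 3 samples of CDH1-selected testis cells, 1 each from wild-type mice of the strains 129, B6 and DBA/2. Per the labels' protocols, testes were dissociated with collagenase and trypsin, cells were bound by the anti-CDH1 antibody ECCD2 and collected on magnetic beads, and total RNA was amplified and biotin labelled for the array. Whether cells of several animals were pooled is not given in the sources used here.

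Per the file headers, the array was the Affymetrix mouse gene 1.0 ST array with annotation on genome build mm9, and coordinates are given on that build. The deposited table gave, for each of 28856 transcript clusters (here called probe sets), an intensity on a linear scale that the authors named raw. These intensities had near-equal quantiles on the 3 arrays and the same lowest value, 27.17, so they were already on a common scale. The background correction, between-array normalization and probe summarization are not given in the sources used here. The same table held a log2 value that the authors named normalized. It equalled log2 of the intensity minus the median of the 3 arrays for that probe set, to within 6.5e-07. The series matrix held the same log2 values as deposited in the table. Per the series design text, the authors compared 129 with B6 and with DBA/2 in GeneSpring and kept genes at a false discovery rate of at most 20% and at least 2-fold. A false discovery rate cannot be computed from 1 array per strain, so that criterion was not applied here.

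Log2 differences between arrays were computed from the intensities, with no pseudocount. Because the authors' centring subtracts 1 value per probe set, it cancels in each difference. Values were exactly equal on all 3 arrays for 7202 probe sets (25.0%) and on exactly 2 arrays for 8789 (30.5%), so many differences are exactly 0.00. Of the probe sets, 22430 had 1 gene symbol, 2824 had several symbols or gene identifiers and 3602 had none. Apart from the shared globin and Nnt probe sets, given as shared, and the gene families of the closing section, no gene was named from a probe set with several. The gene identifiers of 21607 matched a name table of assembly GRCm38.p6, used for names only, which renamed 2460. Where a symbol had several probe sets (1305 of 20193 genes), the one with the highest mean was used.

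A gene entered a comparison if its signal reached the median of the 1-symbol probe sets on at least 1 of the arrays compared, which was 313.3 for 129, 305.6 for B6 and 314.3 for DBA/2. The table gives no detection calls. Olfactory and vomeronasal receptor probe sets, 1245 in number and taken as a guide to unexpressed genes, had a median signal of 53.4 and a 95th percentile of 152.0. Genes at least 2-fold apart were counted in each direction, for each pair and for each strain against both others. No p-values were computed. For 29 gene lists, the median log2 difference of members passing the filter was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. For the shared 129 array, the 3 values of each gene were exchanged at random in 1000 draws.

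The comparisons, thresholds, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named the 10 genes with the largest increase and the 10 with the largest decrease per pair among those at least 2-fold apart, 8 higher and 8 lower per strain set apart from both others, and up to 4 members per list and comparison plus all members at least 2-fold apart. It always named Cdh1, Gfra1, Kit, Zbtb16, Stra8, Sycp3, Ddx4, Actb, Gapdh, Nnt and Glo1, and left out predicted, receptor, immunoglobulin, small RNA and pseudogene symbols. Named outside it, after their values were seen, are Ret, Egr2 and Etv5 of the lists, the shared globin and Nnt probe sets, and the multi-target groups described in the closing section. An item that the rule names is not reported here.

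Alternatives were a 1.5-fold and a 3-fold rule, no level filter, filters at the 20th and 75th percentiles, centring each array on its median, quantile normalization, the series matrix values, every probe set on its own, the median over probe sets, and leaving out predicted genes. Random lists were also matched in 10 bins. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting step was tested on simulated data for 129 against B6, with 200 genes changed and noise of 0.1 on the log2 scale, over 10274 genes. It called 95.5% of genes changed 2.5-fold, 100.0% of those changed 4-fold, none of those changed 1.5-fold and none of the unchanged genes. The changed genes were drawn from the brighter genes, and the real noise is not known without replicates. The simulation checks the counting step and gives no rate of false calls for the real arrays.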

Results

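Gene expression was measured with the Affymetrix mouse gene 1.0 ST array in testis cells of 3 inbred mouse strains, 129, B6 and DBA/2. The cells were labelled spermatogonia, the mitotic germ cells of the testis, and had been selected with an antibody against CDH1 (E-cadherin, an adhesion protein on their surface). All mice were wild type and the testes carried the age label 12 dpc, an abbreviation the labels do not spell out. There was 1 array per strain, so there were no replicates. Every difference below is a difference between single arrays, has no replicate error and no test, and was called by a 2-fold rule alone. The median signal was 262.0 on the 129 array, 260.5 on the B6 array and 257.4 on the DBA/2 array. The number of arrays limits the precision.

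The selected fractions carried germ cell transcripts at high signal on all 3 arrays. The RNA helicase gene Ddx4 had signals of 4300.1 in 129, 4524 in B6 and 4816 in DBA/2, and Zbtb16, a transcription factor of undifferentiated spermatogonia, had 4505, 4383 and 4575. Cdh1, the antigen of the selection, had 577.7, 449.2 and 656.1. The receptor gene Kit, a marker of differentiating spermatogonia, had 2820.0, 2382 and 2225. The meiotic entry gene Stra8 (939.7), Gapdh (14491) and Actb (16668) had the same value on each array. Sertoli cell transcripts were also present, with Sox9 at 3952, 4439.7 and 2768. Sycp3, which the naming rule always includes, was measured only by a probe set shared with a neighbouring gene and is not reported.

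Over genes passing the level filter, the arrays differed least between 129 and B6. The standard deviation of the log2 differences over genes passing the level filter was 0.19 for 129 against B6, 0.26 for 129 against DBA/2 and 0.28 for DBA/2 against B6. Within 1.5-fold lay 98.3%, 96.2% and 95.7% of genes. Correlations across genes, which are not independent replicates, were 0.987, 0.973 and 0.971. Over all 28856 probe sets with no filter the order by 2-fold counts was another. In 129 against B6, 28 were at least 2-fold higher and 334 lower, against 51 and 106 for 129 and DBA/2 and 91 and 356 for DBA/2 and B6. Most of this change came from multi-target probe sets, whose probes match several places in the genome, with 2 higher and 306 lower in 129 than in B6. Over the 25679 single-target probe sets with no filter the counts were 26 and 28, 37 and 59, and 85 and 61, again fewest for 129 and B6.

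The first comparison of the series design set 129 against B6. Of 10245 genes, 21 were at least 2-fold higher and 21 at least 2-fold lower in the 129 array. The macrophage gene Lyz2 (lysozyme) and the lipoprotein lipase gene Lpl were far lower in 129 than in B6, while Slc6a16, a member of the solute carrier 6 transporter family, was far higher. Among genes higher in 129, Slc6a16 (chromosome 7, 52514442 to 52528430, mm9) had signals of 1200.5 in 129 and 227.9 in B6, a log2 difference of 2.40. Plbd1 differed by 2.09, Ak9 by 2.05, the acetylcholine receptor subunit gene Chrna4 by 1.91, Phyhip by 1.63 and the calcium release channel gene Ryr2 by 1.59. The splicing factor gene Snrpa1 differed by 1.53, the ceramidase gene Acer2 by 1.31, Mtres1 by 1.25 and Cd109 by 1.20. Acer2 and Ak9 each had another probe set with a difference of 0.00.

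Among the genes the naming rule allows, Trim12a (chromosome 7, 111392519 to 111464009, mm9) had the most negative log2 difference of 129 from B6, -2.60, with signals of 72.8 and 440.0. Lpl followed at -2.01, Lyz2 at -1.89 and Olfml3 at -1.36. Pdpn (podoplanin) was at -1.30, the cytochrome b5 reductase gene Cyb5r3 at -1.26, Frg1 at -1.23, Churc1 at -1.18 and Clmp at -1.15. Trim12a belongs to a family with near-identical copies, so its value is uncertain.

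The macrophage and leukocyte list had 6 members above the level filter, of which 5 were lower and 1 equal in 129. Its median log2 difference was -0.40. However, 4 of the 6 reached the level filter on the B6 array alone, which favours members lower in 129, and the 2 that reached it on both arrays had a median of -0.02. Lyz2 alone passed the 2-fold rule, and C1qb was at -0.58, Cd68 at -0.42 and Mrc1 at -0.39. With no level filter the median of the 17 measured members was -0.06. The undifferentiated spermatogonia list had a median of 0.02 with 15 of 24 members higher, and no member passed the 2-fold rule in either direction. Bcl6b was at -0.85, Mcam at -0.62, Utf1 at 0.60 and Upp1 at 0.58. The early meiosis list had a median of -0.05, with 13 of 20 members lower, at percentile 0.04 of 10000 random lists matched on mean expression, led by Sycp1 at -0.77 and Dmc1 at -0.39. Immediate early and heat shock genes had a median of 0.13 (percentile 99.9), with 9 of 14 higher, among them Fos at 0.55, Nr4a1 at 0.42 and Hspa1a at 0.38. The GDNF and FGF response list had a median of -0.08 (percentile 0.23), with 8 of 13 lower, among them Spry4 at -0.72. The general germ cell list had a median of -0.03 (percentile 0.38), with 8 of 19 members higher and 10 lower. The Sertoli list was at 0.01, the Leydig list at 0.08 and the peritubular and stromal list at -0.02. Because 27.4% of genes were exactly equal on the 129 and B6 arrays, medians of random lists lie close to 0. A very small median can therefore reach an extreme percentile. The percentiles also treat list members as independent genes. Nnt (nicotinamide nucleotide transhydrogenase) was lower in 129 than in B6, at -0.74, but a probe set it shares with a predicted gene read 0.17, and the B6 sub-strain is not given in the sources used here.

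The second comparison of the design set 129 against DBA/2. Of 10283 genes, 29 were at least 2-fold higher and 41 at least 2-fold lower in the 129 array. The list medians of undifferentiated spermatogonia, the pool that holds the stem cells, and of genes that respond to the growth factors GDNF and FGF were lower in 129. Those of Sertoli, Leydig and peritubular marker genes were higher in 129, although only 1 of 22, 1 of 8 and 3 of 11 members passed the 2-fold rule. The undifferentiated spermatogonia list had a median log2 difference of -0.22, with 22 of 26 members lower (percentile 0.00), and 6 of them passed the 2-fold rule. These were the transcription factor genes T at -1.40, Eomes at -1.12, Lhx1 at -1.08, Bcl6b at -1.05 and the inhibitor of differentiation gene Id4 at -1.02, with the adhesion molecule gene Mcam at -1.01. T and Eomes reached the level filter on the DBA/2 array alone, and among members reaching it on both arrays the median was -0.19, and -0.64 for the GDNF and FGF response list. Gfra1, the GDNF co-receptor gene, was at -0.93, with signals of 1981.1 in 129 and 3768 in DBA/2. The GDNF and FGF response list had a median of -0.66, with 12 of 15 members lower and none higher, 4 of them past the 2-fold rule, and Spry4, a feedback inhibitor of the pathway, at -1.10. This list shares members with the undifferentiated list, among them Gfra1, T, Lhx1 and Bcl6b, so the medians are not separate evidence.

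In the same comparison the general germ cell list had a median of -0.16, with 17 of 19 members lower. Taf7l was at -0.56, Rhox13 at -0.50 and Usp26 at -0.45, and Ddx4 was at -0.16. The Sertoli list had a median of 0.31, with 19 of 22 members higher. Cst9 (cystatin 9) differed by 3.60, although its other probe set, elsewhere on chromosome 2, differed by 0.10. Drd4, Cldn11 and Wt1 differed by 0.79, 0.72 and 0.59. The Leydig list had a median of 0.37, with 6 of 8 higher, led by the steroid hydroxylase gene Cyp17a1 at 1.85 and the cholesterol transport gene Star at 0.81. The peritubular and stromal list had a median of 0.42, with 11 of 11 higher, among them Igfbp7 at 1.43, the proteoglycan gene Dcn (decorin) at 1.13 and the smooth muscle actin gene Acta2 at 1.01. The macrophage and leukocyte list had a median of -0.42 with 4 of 5 lower, but 3 of the 5 reached the level filter on the DBA/2 array alone. With no level filter the medians were 0.00 for macrophage and leukocyte genes and -0.24 for GDNF and FGF response genes, and without the Y chromosome the general germ cell median was -0.26.

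Outside these lists, the genes allowed by the naming rule with the largest excess in 129 over DBA/2 included Zfp951 (2.55), Slc6a16 (2.43), the antiprotease domain gene Wfdc8 (1.72), the proteoglycan gene Bgn (1.56), Ryr2 (1.53), Tktl2 (1.48) and Chrna4 (1.45). Those with the largest deficit included the serpin gene Serpina3a (-4.04), Mid1 (-3.30), Mela (-3.18), Cntn6 (-2.21), the apolipoprotein gene Apoc2 (-1.90), the Wnt antagonist gene Frzb (-1.84), Rpa3 (-1.67), Rgs16 (-1.53) and Barhl2 (-1.51). Serpina3a belongs to a family of close paralogs and is uncertain. Mela had another probe set at -0.87.

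**Figure D1:**
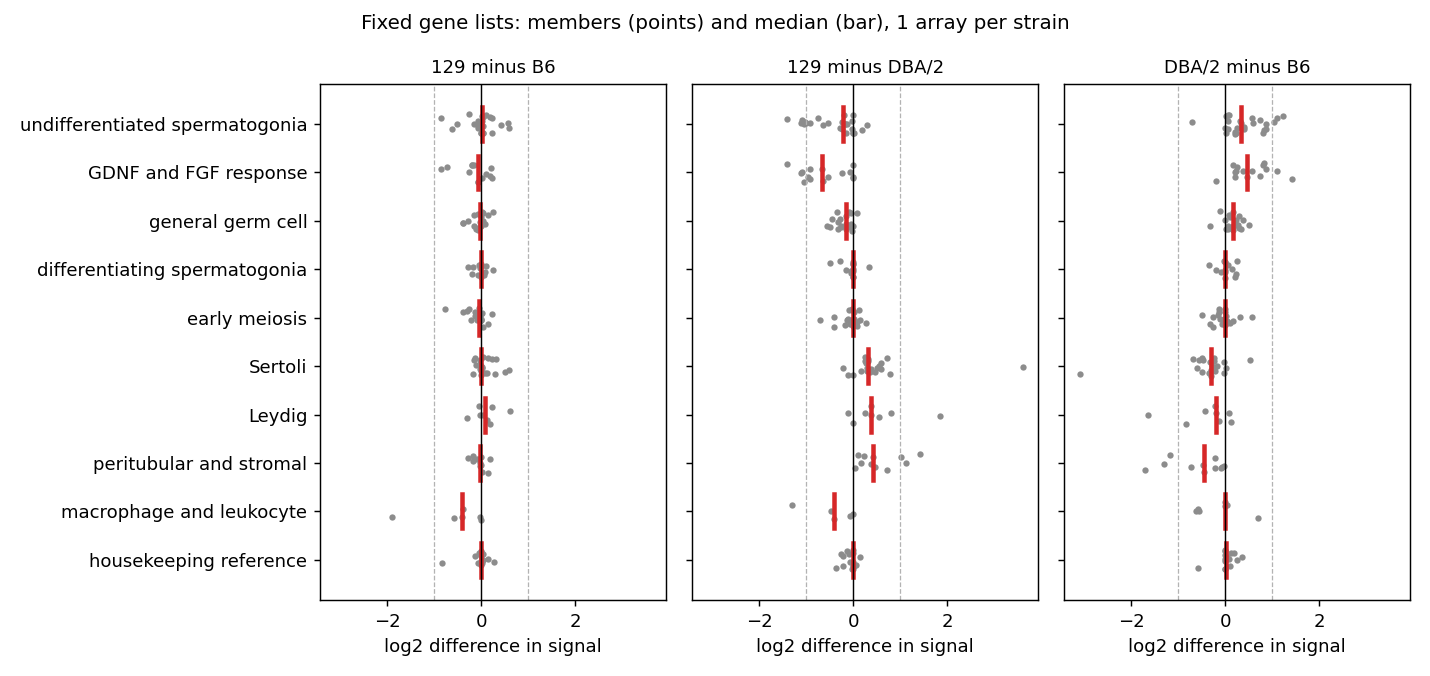
Log2 differences in signal of the members of 10 gene lists that pass the level filter (grey points) and the list median (red bar) in 3 comparisons of single arrays. Dashed lines mark 2-fold. In the comparison of DBA/2 with B6, the medians of the undifferentiated and GDNF response lists lie at 0.32 and 0.47 and those of the Sertoli and stromal lists at -0.30 and -0.46.

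The remaining pair, DBA/2 against B6, held the most genes past the 2-fold rule, 48 higher and 47 lower in DBA/2 of 10289. The list medians of undifferentiated spermatogonia and of the GDNF and FGF response were higher in the DBA/2 array, and those of Sertoli, Leydig and stromal marker genes were lower, as they were against 129. Of the latter lists, 1 of 22, 1 of 8 and 3 of 11 members passed the 2-fold rule. The comparisons of DBA/2 with B6 and with 129 share the single DBA/2 array, so they are not separate evidence. Differentiating spermatogonia genes had a median of 0.00 in both comparisons, which exact ties favour. Of 13 members in 129 minus DBA/2, 7 were equal, 5 lower and 1 higher in 129. Of 14 in DBA/2 minus B6, 5 were equal, 5 higher and 4 lower in DBA/2. The undifferentiated spermatogonia list had a median of 0.32 with 24 of 26 members higher (percentile 100), and Eomes at 1.23, T at 1.10 and Id4 at 1.03 passed the 2-fold rule, the first and second of them reaching the level filter on the DBA/2 array alone. Gfra1 differed by 0.86, Upp1 by 0.87 and Lhx1 by 0.82. The GDNF and FGF response list had a median of 0.47, with 14 of 15 higher and 2 past the 2-fold rule. The phosphatase gene Dusp4, induced by the pathway and also above the filter on the DBA/2 array alone, differed by 1.41, Egr2 by 0.81, Ret, the GDNF receptor kinase gene, by 0.73, and Etv5 by 0.56. The general germ cell list had a median of 0.17 with 16 of 19 higher, and Zbtb16 and Ddx4 differed by 0.06 and 0.09.

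The Sertoli list had a median of -0.30 in DBA/2 against B6, with 20 of 22 members lower, among them Sox9 at -0.68 and Wt1 at -0.59. Cst9 was at -3.09, while its other probe set, elsewhere on chromosome 2, was at 0.11. The Leydig list had a median of -0.20, with Cyp17a1 at -1.65 and Hsd17b3 at -0.84. The peritubular and stromal list had a median of -0.46, with 11 of 11 lower, among them Igfbp7 at -1.70, Dcn at -1.29 and Acta2 at -1.18. Macrophage and leukocyte genes had a median of 0.00, with 3 of 7 lower, and endothelial genes 0.03, with 2 of 4 lower. Probe sets shared by paralogous globin genes, which are uncertain and were chosen after their values were seen, had median signals of 922.95 in 129, 657.5 in B6 and 405.8 in DBA/2 for alpha globin and 486.9, 392.05 and 273.85 for beta globin. Among members reaching the filter on both arrays the undifferentiated median was 0.29 and the GDNF and FGF median 0.38, and with no level filter the latter was 0.23 and the stromal median -0.28. At the 75th percentile filter the undifferentiated median was 0.20, the general germ cell median 0.08, the Leydig median -0.84 and the stromal median -1.18. The retinoic acid pathway list had a median of -0.08, with 8 of 13 lower and none higher, and the retinol carrier gene Stra6 was at -1.02. The named genes with the largest excess in DBA/2 were Serpina3a (4.03), Mela (3.31), Mid1 (3.01), Ak9 (2.64), the homeobox gene Barhl2 (2.52), Snrpa1 (1.95), Cfap54 (1.91), Frzb (1.90), Cd109 (1.87) and Apoc2 (1.84), although another probe set of Ak9 differed by 0.02 and another of Mela by 0.88. Those with the largest deficit were Cst9, Trim12a (-2.73), Zfp951 (-2.58), Lpl (-2.02), Bgn (-1.70), Igfbp7, Cyp17a1, Spp1 (-1.54), Mme (-1.48) and Tktl2 (-1.46).

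Across all 3 strains, the DBA/2 array had the most genes set apart from both others by at least 2-fold, 22 higher and 16 lower. The 129 array had 5 higher and 6 lower, and the B6 array 11 higher and 11 lower. The 5 higher in 129 were Slc6a16, Ryr2, Chrna4, Phyhip and Wfdc8. Genes lower in 129 than in both included Lyz2, Frg1, Churc1 and the amino acid transporter gene Slc1a5. Genes lower in B6 than in both others included Ak9, Plbd1, Snrpa1, Mtres1, Cd109, the growth factor gene Bmp4, Zfp69 and Cfap54. Trim12a, Lpl, Cyb5r3 and Olfml3 were higher in B6 than in both. Strain variants under the probes could alter single-gene values and were not checked for any named gene. Genes lower in DBA/2 than in both others included the receptor genes Npr1 and Ednra. With each array centred on its median, the B6 counts were 15 higher and 9 lower. With the filter on the mean of the arrays, 2 genes were higher in 129 and 3 higher in B6 than in both others.

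**Figure D2:**
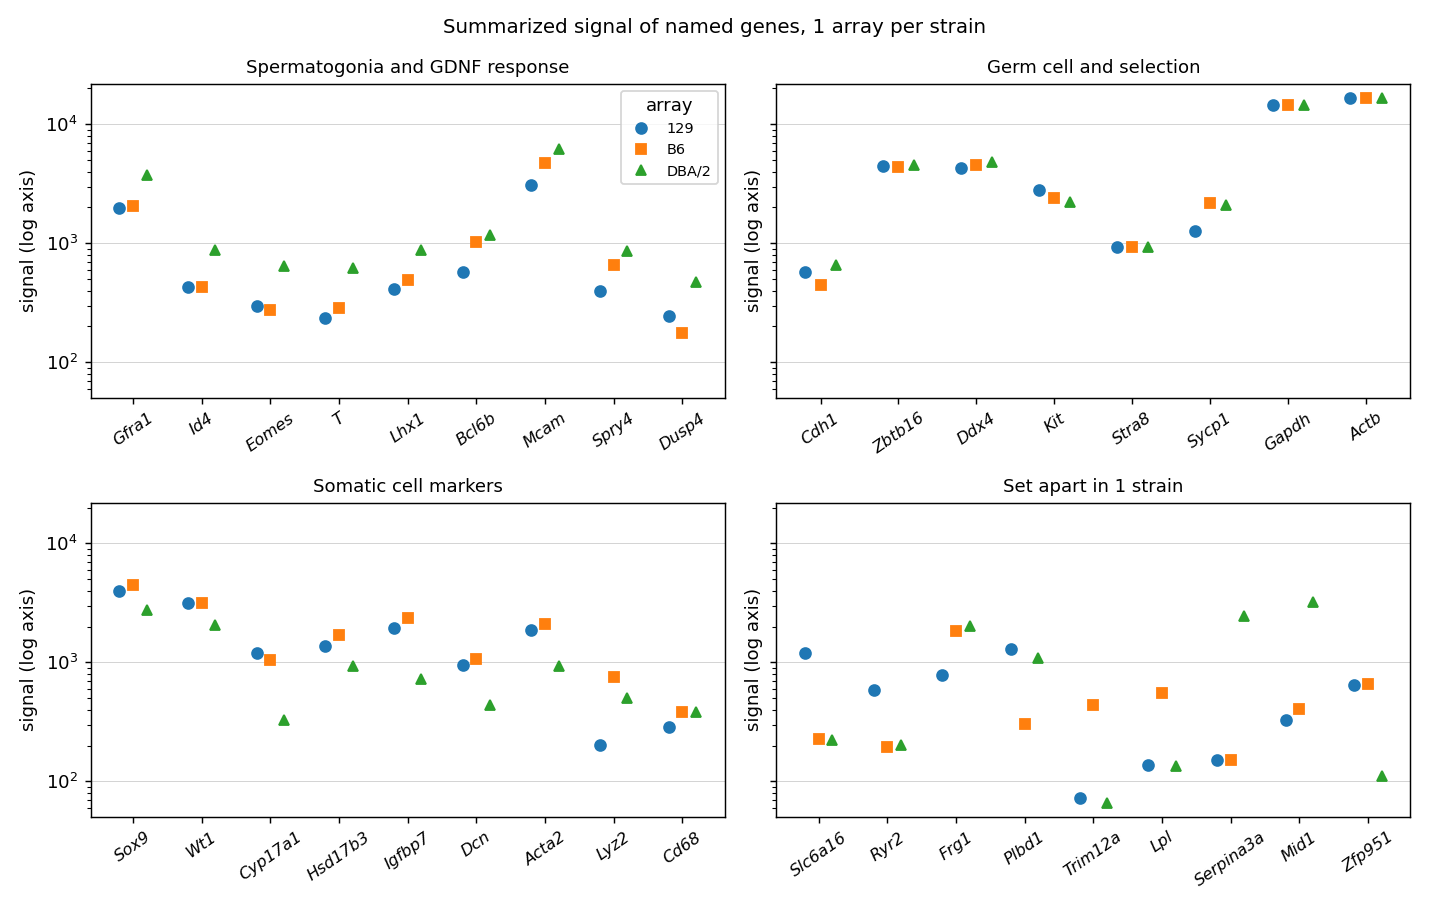
Summarized signal (log axis) of named genes on the 129, B6 and DBA/2 arrays, 1 point per array. Gfra1 reads 1981.1, 2071 and 3768, and Serpina3a reads 149.9, 150.7 and 2462.

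The comparisons of 129 with B6 and with DBA/2 share the 129 array. Across 10368 genes their log2 differences correlated at r = 0.29, with a covariance of 0.0144. Exchanging the 3 arrays at random within each gene gave a mean r of 0.50 (95% of draws from 0.452 to 0.546) and a covariance of 0.0304 (0.0266 to 0.0343), both above the observed values. The 5 genes higher in 129 than in both stand beside 12.6 under that exchange (7 to 18) and 0.0587 for independent lists, and the 6 lower beside 11.02 (6 to 16) and 0.083. By construction the exchange gives an r near 0.50 and counts near the average over the 3 strains. It therefore cannot test whether 129 stands apart. Part or all of the excess over independent lists may come from the shared array, which cannot be split.

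In the order 129 against B6, 129 against DBA/2 and DBA/2 against B6, medians of the other fixed lists were 0.02, -0.20 and 0.38 for surface markers used to enrich spermatogonia (percentiles 80.8, 0.30 and 100), and 0.00, -0.07 and 0.32 for pluripotency genes (38.3, 23.9 and 99.4). The 10 surface markers that passed the filter include Gfra1 and Mcam of the undifferentiated list, and 6 pluripotency genes passed it in DBA/2 against B6. Under the alternatives, the DBA/2 minus B6 median fell as low as 0.19 for surface markers and 0.09 for pluripotency genes. The surface marker median for 129 minus DBA/2 came as near to 0 as -0.09. Medians were 0.04, -0.11 and 0.15 for piRNA and DNA methylation genes, with Gtsf1 at -0.07, -0.69 and 0.62. Differentiating spermatogonia genes and imprinted genes had medians of 0.00 in each comparison. Late spermatocyte and spermatid genes were at 0.02, 0.00 and 0.00, and cell cycle genes at 0.00, -0.06 and 0.02. Cyclins D and CDK inhibitors were at 0.00, 0.00 and 0.04, and genes of germ cell tumour and pluripotency restraint at 0.01, 0.00 and 0.06. Reactive oxygen and antioxidant genes were at 0.00 in each comparison, with Gsr (glutathione reductase) at 0.93, 0.18 and 0.75. Junction and adhesion genes were at 0.00 in each comparison, and interferon response genes at 0.01, 0.00 and 0.03. Classical and nonclassical MHC genes were at 0.00, 0.03 and -0.07, with B2m at -0.83, -0.25 and -0.58. Y-linked genes and Xist were at 0.00, 0.00 and 0.03, and housekeeping genes at 0.00, 0.00 and 0.02. Endothelial genes were at 0.00, -0.03 and 0.03. Retinoic acid genes were at -0.04 and 0.11 in the 129 comparisons, early meiosis genes at 0.00 and -0.01 in the DBA/2 comparisons, and immediate early genes at 0.16 and 0.00 there. Epididymal and rete epithelium genes were at 0.00 against B6 in 129 and -0.17 in DBA/2, with too few members for the other pair, and no erythroid median could be taken because no single-gene probe set of that list passed the filter. Genes with a known allele difference between inbred strains were at 0.04, 0.00 and 0.05. Of these, Glo1 (glyoxalase 1) was higher in DBA/2 than in B6 by 0.84 in a multi-target probe set, which makes it uncertain, and Nnt was lower by a log2 difference of -1.05, against -0.06 in its shared probe set.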

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

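The filter at the 95th percentile of receptor probe sets, the filter on the mean of the arrays, the restriction to single-target probe sets and the omission of the Y chromosome were chosen after seeing the data. No paired analysis was possible because there was 1 array per strain, and no array could be left out. The series matrix values changed nothing, since they are the same values. The standard deviations and the correlation stayed within the tolerances set (1.5 times and 0.1), and the latter ranged from 0.2881 to 0.3094. Of the list medians, 928 of 971 moved by less than 0.1, and of the named genes' differences 3000 of 3015 by less than 1.5-fold. Both shares are high by construction. For the lists, the series matrix setting moves nothing and many medians lie near 0. The GDNF and FGF median for 129 minus DBA/2 ranged from -0.72 to -0.24 under the alternatives. The stromal median for DBA/2 minus B6 ranged from -1.18 to -0.28. The level filters were not applied to named genes, and the probe set settings cannot change a gene with a single probe set. All larger changes were in Acer2, Ak9, Cst9 and Mela, which have several probe sets. Centring moved the median of all genes by at most 0.04 on the log2 scale. Low signals and the lack of detection calls limit dim genes, which the filter settings show.

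The counts follow the fold rule by construction. For 129 against B6, 129 against DBA/2 and DBA/2 against B6 in turn, the 1.5-fold rule gave 94 higher and 77 lower, 188 and 198, and 231 and 208. The 3-fold rule gave 6 and 8, 6 and 8, and 15 and 12. Set apart from both others in 129, B6 and DBA/2 in turn were 28 and 28, 38 and 35, and 95 and 103 genes at 1.5-fold, and 1 and 1, 6 and 2, and 5 and 4 at 3-fold. The 75th percentile filter, which tests fewer genes, gave 8 and 7, 15 and 16, and 13 and 24 for the pairs, and 2 and 2, 3 and 5, and 7 higher for the strains. Genes higher in B6 than in both others numbered 17 with no filter, 19 with every probe set on its own, 4 without predicted genes and 5 over single-target probe sets. With the filter on the mean of the arrays, 2 genes were higher in 129 and 3 higher in B6 than in both others. Genes lower in 129 than in both others numbered 11 with every probe set on its own, and those lower in 129 than in B6 numbered 13 without predicted genes.

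With no level filter, the macrophage median was -0.0625 against B6 and 0.00 against DBA/2 in 129, the stromal median 0.30 for 129 minus DBA/2 and -0.28 for DBA/2 minus B6, and the GDNF and FGF median -0.24 and 0.23. At the 20th percentile these were -0.0584 and 0.00 for macrophage, -0.34 for stromal in DBA/2 minus B6, and -0.43 and 0.26 for GDNF and FGF, and Leydig in DBA/2 minus B6 was -0.32. At the receptor percentile they were -0.0625 and 0.00 for macrophage, -0.35 for stromal, and -0.48 and 0.32 for GDNF and FGF. At the 75th percentile, 129 minus DBA/2 was 0.55 for Leydig and 0.62 for stromal, and DBA/2 minus B6 was 0.20 for undifferentiated spermatogonia, -0.84 for Leydig and -1.18 for stromal. With the filter on the mean of the arrays the stromal median for DBA/2 minus B6 was -0.34, and the macrophage median in 129 stayed at -0.40 against B6. Without the Y chromosome the general germ cell median for 129 minus DBA/2 was -0.26. Cst9 in DBA/2 against B6 reversed to 0.11 in its other probe set. That probe set lies elsewhere on chromosome 2 (149182408 to 149183141, against 148660883 to 148664473, mm9) and may not measure the same transcript. The cause was not tested.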

Other observations

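The tests of the undifferentiated spermatogonia and somatic marker pattern and of the multi-target pattern were chosen after the results were seen. For the multi-target pattern the bounds were set with the values already known. The test of equal values by odd and even probe number was set before its result was seen. The groups of probe sets described next were chosen after their values were seen.

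Some groups of probe sets whose probes match several places in the genome set the B6 array apart. Over all 28856 probe sets with no level filter, 334 were at least 2-fold lower and 28 higher in 129 than in B6. Of the 3174 multi-target probe sets, 306 were lower and 2 higher in 129 than in B6, and 295 were lower and 6 higher in DBA/2. Of the lower ones, 126 in 129 and 132 in DBA/2 lay in a small nucleolar RNA region of chromosome 7, whose 142 multi-target probe sets held 44 distinct sets of values, and 59 and 60 lay on unplaced Y sequence. Probe sets of the small nucleolar RNA family Snord115, which lies in an imprinted region of chromosome 7, had median signals of 50.05 in 129, 276.3 in B6 and 47.3 in DBA/2. The neighbouring Snord116 family had 83.5, 813.6 and 333.7. These 16 and 21 probe sets held only 3 distinct sets of values each, so they are not independent. The Y-linked spermatid gene family Ssty had medians of 153.2, 558.6 and 96.9 over 20 probe sets. By contrast, 16 single-target probe sets of the Y chromosome had medians of 407.2, 368.4 and 374.0, with none 2-fold apart from B6. Vomeronasal receptor probe sets had medians of 76.7, 131.0 and 71.1 when multi-target and 43.1, 43.7 and 42.2 when single-target.

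Higher list medians of undifferentiated spermatogonia and of the GDNF and FGF response in DBA/2 than in B6 went together with lower ones of somatic markers. A smaller somatic share as the whole cause would raise all germ cell genes alike. The 31 undifferentiated and GDNF response genes exceeded 54 genes of the other germ cell lists by 0.38 in median log2 difference. The lower end of the 95% bootstrap interval over genes ran from 0.19 to 0.20 in 12 random seeds. Among members passing the filter on both arrays the excess was 0.32. This excess cannot decide the question, because the differentiating, early meiosis and late spermatid medians of 0.00, -0.01 and 0.00 were known beforehand. Those lists also follow germ cell stage and hold exact ties, so they need not rise with the germ cell share. Over the general germ cell list alone the excess was 0.18 with lower ends from -0.0104 to -0.0047. A smaller somatic share is therefore not excluded as part or whole of the rise. The intervals are over genes on single arrays and do not measure the spread between samples. A smaller share of every somatic cell type stays open for the somatic markers, since 11 macrophage and endothelial markers had a median of 0.00 with quartiles of -0.35 and 0.05, overlapping -0.50 to -0.18 for 41 Sertoli, Leydig and stromal markers, and a strain difference in the stem cell pool is untested. Globin probe sets, lower in DBA/2 than in B6 by median log2 differences of 0.70 for alpha and 0.52 for beta globin, fell in the same direction as the Sertoli markers, but are only 2 multi-target probe sets each. They did not follow the Sertoli markers between 129 and B6. There the B6 minus 129 medians were -0.49 for alpha and -0.31 for beta globin, while the Sertoli median for 129 minus B6 was 0.01.

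For the multi-target excess in B6, mismatch of probes designed on B6 sequence could lower the other strains. Single-target probe sets at least 2-fold apart showed no such lean, with 51.9% lower in 129 and 41.8% lower in DBA/2 than in B6, but gene families may differ more between strains than single genes. Genomic DNA in the B6 sample could raise silent multi-copy families. The 558 dim multi-target probe sets outside chromosome 7 and the Y were higher in B6 by a median of 0.0329 over 129 and 0.09 over DBA/2, with upper quartiles of 0.26 and 0.34, which leaves it open. A difference in copy number or expression between strains was not tested.

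Exactly equal values on several arrays are consistent with summarization by median polish over only 3 arrays. Simulated noise summarized that way gave 80.3% of probe sets equal on all 3 arrays for odd and 72.9% for even probe numbers. Averaging the probes gave none, which is certain for continuous values. In the deposited values, probe sets of 20 to 35 probes were equal in 29.8% for odd and 22.3% for even numbers, a difference of 7.53 percentage points (95% interval 6.33 to 8.73). The simulation held noise alone and gave far higher shares, so only the direction from odd to even was compared. A difference of 0.00 may therefore hide a small one. No biological explanation of the equal values was tested.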
